A study of Mus musculus with 23 samples.

How the data were processed

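RNA-seq libraries from scrapings of the proximal small intestine of 23 mice were analysed, 12 from mice fed the galactose diet and 11 from mice fed the glucose diet, each library from a separate mouse. Per the submitters' processing notes, reads were processed with STAR and HTSeq on the genome build GRCm39. The tool versions, the annotation release, the strand setting and any read filters are not given in the sources used here. The authors deposited 1 table of raw read counts per mouse, with 55416 gene rows and 5 rows that name no gene. Those 5 rows held 13.5% of all reads and were left out of library sizes and tests. Gene symbols were taken from the supplied name table by Ensembl identifier. A symbol was found for 52083 rows, which is 94.0% of the gene rows and holds 99.8% of the counts in genes. No coordinates are given, because the annotation at hand is of another build. Transcript length was taken by identifier from that annotation, as the longest transcript of each gene.

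Libraries held 15382583 to 17174721 counts in genes. All 121 pairs of libraries within a diet group were compared by a chi-square statistic over genes with a mean count of at least 10. Its value per degree of freedom lay between 12.9 and 51.3, so no library was a copy of another of its group. Pairs across the diets were not compared. The replicate numbers follow the order of deposit and pair no mice.

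The diets were compared with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr, which left 13405, and libraries were scaled by TMM. The quasi-likelihood F test was fitted to all 23 libraries with diet as the only term, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Fold changes are log2 values, galactose minus glucose, with their standard errors (SE). Counts-per-million (CPM) are given as mean ± SD over the libraries of a group. In simulated counts for 13405 genes, 200 of which were changed, the test recovered 37.3% of genes changed 1.25-fold, 70.1% of those changed 1.5-fold and 87.9% of those changed 2-fold. Unchanged genes made up 6.43% of its calls. The simulation drew genes independently, and in real libraries genes move together.

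Before the data were examined, 66 gene lists for pathways, cell types and sample state were fixed, of which 65 had at least 3 tested members. Each was set against all other tested genes with camera (limma 3.58.1) at a preset correlation of 0.01. The test was repeated with an estimated correlation and with fry, which asks whether the genes of a list move one way. A list's score in a library is the mean log2 CPM of its tested members with a prior count of 2. Scores were compared between diets by a permutation test with 100000 resamples, added after the list calls had been seen. Counts of members "adjusted over the list alone" use Benjamini-Hochberg within that list.

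The genes named were set by a rule fixed at the same time. It takes the 10 genes higher and the 10 lower on galactose with the largest changes among those passing the threshold. Where fewer pass, it takes those of smallest unadjusted p with a mean of at least 1 CPM, given as values. Predicted genes, unnamed identifiers and immunoglobulin or T cell receptor segments were left out of that part. It adds all tested genes of galactose catabolism, the sugar transporters and disaccharidases of at least 1 CPM, and the 4 members of smallest p of each list called. Some genes that the rule takes are not reported here.

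Library composition was compared by two-sided permutation tests with 100000 resamples on 8 measures, and on 6 more that were added after the files were seen. The length slope of a library is the slope of its log2 CPM, relative to the mean of all libraries, on log2 transcript length over genes. Alternatives tried were other scalings, DESeq2 1.42.0, limma-voom with and without sample quality weights, other count filters, a robust fit, 6 surrogate variables (sva 3.50.0) and scores for other tissue, gut position and the clock as covariates. Each library was also left out in turn. The length slope and the GC slope as covariates were added after a length trend had been seen. Whether that trend accounts for a list's difference was first tested on 10000 random lists matched on length and expression. After those values had been seen, the test was replaced by one per library, because genes of a list move together and are not replicates. It gives the diet difference in a list's score with the length slope held, and also after taking off the shift that each library's length slope predicts for genes as long as the list's members. The rule for reading this test was changed 3 times with earlier values known. The subtraction came with the change before the last, and the last asks that a list's difference exclude 0 before correction. The folds of the calls made without galactose replicate 7 were also added late, on genes picked by those calls. They do not overturn the rule set beforehand, which reads in favour of the length trend. The diets were also compared in 100 splits of the libraries (30 with DESeq2), the real one included. Python 3.11.15 with scipy 1.17.1, numpy 2.4.6 and matplotlib 3.10.9 was used for the permutation tests of library composition and for plots. The permutation tests of list scores and of correlations were run in R.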

Results

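Gene expression was measured by RNA-seq in mucosal scrapings of the proximal small intestine of C57BL/6JRccHsd mice labelled female. From day 21 of age, after weaning, the mice ate for 3 weeks either a diet with 16% of energy from galactose and 16% from glucose (n = 12) or one with 32% of energy from glucose (n = 11). Tissue was taken on day 42. Libraries held 16217808 ± 484497 counts in genes on galactose and 16456054 ± 570744 on glucose (SD). The comparison asks how the proximal intestine differs when galactose replaces part of the dietary glucose in young mice.

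By edgeR no single gene passed the test between the diets. Lists of sugar metabolism, respiration and interferon genes lay higher on galactose by camera at its preset correlation, but 0 of 65 lists were called with an estimated correlation (smallest adjusted p = 0.387). The smallest p-values among genes higher on galactose belonged to Fbp1, a fructose bisphosphatase of gluconeogenesis, and to Kctd14 and Id2. Fbp1 had 137 ± 28.5 CPM on galactose and 91.4 ± 20.3 CPM on glucose, a log2 difference of 0.59 ± 0.12 (SE), and lay above the glucose median in 12 of 12 galactose libraries. Khk, the ketohexokinase that phosphorylates fructose, had 737 ± 104 CPM against 562.0 ± 87.2 CPM (log2 difference 0.39 ± 0.09). Among genes lower on galactose, Slc28a1, a nucleoside transporter, had 42.2 ± 10.9 CPM against 69.2 ± 25.2 CPM (log2 difference -0.71 ± 0.17), and Me1, the malic enzyme that supplies NADPH, had 12.8 ± 4.42 CPM against 21.0 ± 6.57 CPM (-0.71 ± 0.17).

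edgeR's quasi-likelihood test called 0 of 13405 genes, with a smallest adjusted p of 0.135 that 28 genes shared. At an unadjusted p under 0.05 there were 1924 genes, 1157 higher and 767 lower on galactose, where chance gives 670. DESeq2 called 87 genes (64 higher, 23 lower), limma-voom 0, and limma-voom with sample quality weights 167 (142 higher, 25 lower). Without galactose replicate 7, edgeR called 219 genes, 175 higher and 44 lower. That replicate was the only library whose removal gave any calls, so counts without it, here and below, are no separate support. Genes called higher had a median transcript length of 1710 bases with DESeq2, 1698 with quality weights and 1577 without replicate 7. Those called lower had 4300, 5234 and 5364 bases, against 3228 for all tested genes. The other genes named by rank among those higher on galactose by edgeR were Psmb3 (0.35), Slc22a13b-ps (0.68), Ifi35 (0.35), Mydgf (0.29) and Lamtor3 (0.27), with Kctd14 at 0.55 and Id2 at 0.27. Among those lower, Paqr7 stood at -0.59, Olfr165 at -0.54, Ids at -0.36, Pigh at -0.32, Zfp770 at -0.64, Ptprn at -0.44 and Castor2 at -0.34 (log2 differences).

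**Figure D1:**
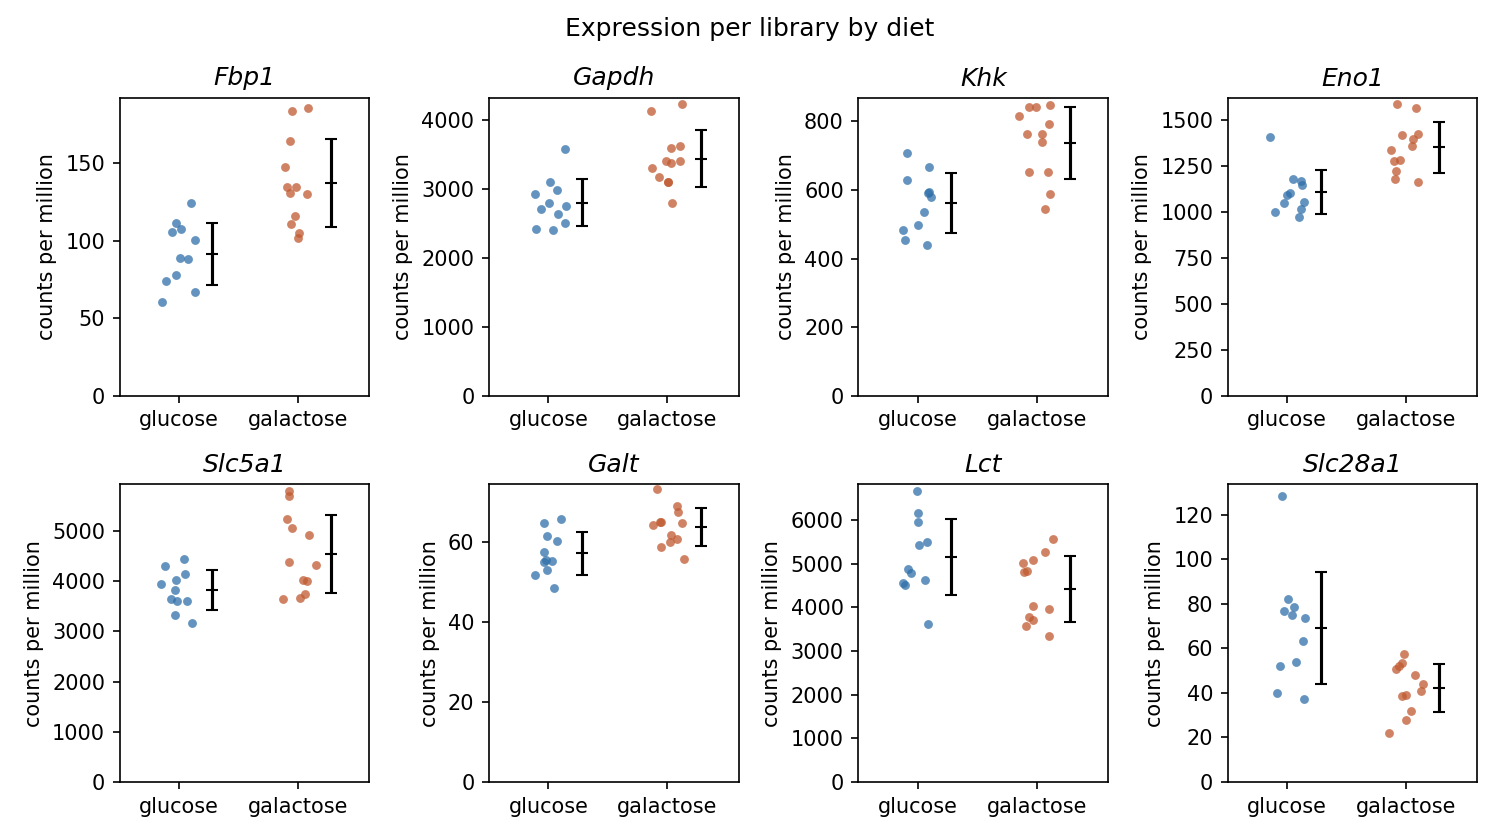
Counts-per-million (CPM) of 8 named genes in each library, with the glucose libraries (n = 11) in blue and the galactose libraries (n = 12) in orange, and black marks for the mean ± SD beside the points. Fbp1, Gapdh, Eno1 and Galt lay above the glucose median in 12 of 12 galactose libraries, and Slc28a1 below it in 12 of 12. By edgeR 0 of the 8 passed the adjusted test, while Fbp1, Khk, Eno1 and Gapdh did by DESeq2 and by limma-voom with quality weights, and Slc28a1 by DESeq2.

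Of 65 gene lists tested, camera called 20 at its preset correlation, 12 higher and 8 lower on galactose. With an estimated correlation it called 0, and 7 lists had an unadjusted p under 0.05. fry called 4 of these lists, oxidative phosphorylation, the tricarboxylic acid cycle, glycolysis and the targets of the sugar-responsive factor ChREBP. The permutation test of list scores called 0, at a smallest adjusted p of 0.0543.

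Lists of sugar metabolism genes were called higher on galactose by camera at its preset correlation, but not with an estimated one. The permutation test of their scores gave an adjusted p of 0.110 for glycolysis and for fructose metabolism. It gave 0.0543 for the ChREBP targets and 0.203 for gluconeogenesis. In the glycolysis list 18 of 23 members had positive differences (median log2 difference 0.16), and 9 passed by edgeR when adjusted over the list alone. Over all genes tested 0 passed by edgeR, 6 by DESeq2, 5 by limma-voom with quality weights and 6 by edgeR without galactose replicate 7. Its adjusted p was 6.77e-08 with the preset and 0.387 with an estimated correlation. Its members included Eno1 (0.29 ± 0.07), Gapdh (0.29 ± 0.07) and Gpi1 (0.26 ± 0.07). The ChREBP targets had 11 of 12 members higher (median 0.16), and their mean lay above the glucose median in 12 of 12 galactose libraries. Among them were Tkfc (0.30 ± 0.10) and Pklr (0.19 ± 0.08), and 3 members passed when adjusted over the list alone (adjusted p = 0.387 for the list with an estimated correlation). The fructose metabolism list (median 0.21, 4 of 6 higher) shares members such as Khk and Tkfc with it, and the adjusted p was 0.387 with an estimated correlation. In the gluconeogenesis list (median 0.13, 5 of 8 higher), Slc37a4 had 0.31 ± 0.08, Fbp2 0.12 ± 0.06 and G6pc 0.29 ± 0.16, and the adjusted p was likewise 0.387 with an estimated correlation.

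The nuclear-encoded genes of oxidative phosphorylation were higher in all 72 of 72 members (median log2 difference 0.21), and 61 passed by edgeR when adjusted over the list alone. Over all genes tested 0 passed by edgeR, 7 by DESeq2, 26 by limma-voom with quality weights and 34 by edgeR without galactose replicate 7. That replicate had the lowest score of this list on galactose, 6.95, so leaving it out widens the difference by itself. Examples were Ndufa11 (0.27 ± 0.06), Cox5b (0.29 ± 0.07), Ndufv1 (0.24 ± 0.06) and Uqcrq (0.31 ± 0.08), subunits of the respiratory chain. The tricarboxylic acid cycle list had 20 of 22 members higher (median 0.13), 8 of them when adjusted over the list alone, with Pdhb (0.27), Sdhb (0.24), Sdhd (0.26) and Fh1 (0.21) first. Both lists had an adjusted p of 0.387 with an estimated correlation. Cytosolic ribosomal protein genes were higher in 62 of 64 members (median 0.13, adjusted p = 0.601 with an estimated correlation), led by Rpl11 (0.23), Rps15 (0.26), Rps14 (0.30) and Rps25 (0.18). The oxidative phosphorylation and ribosomal lists consist of short transcripts (median 1025 and 1124 bases, against 3228 for all tested genes), and short transcripts as a class were higher on galactose. With all tested genes parted into 10 groups by length, the shortest group had a median log2 difference of 0.12 and the longest -0.11. The length slope per library was -0.0289 ± 0.0553 on galactose and 0.0315 ± 0.0450 on glucose (SD; permutation p = 0.0115, adjusted p = 0.0446 over 6 measures added after the files were seen). With that slope as a covariate the ribosomal list turned to a median of -0.10, with Rps15 at -0.0468, Rps14 at -0.0470 and Rps25 at -0.00222, and oxidative phosphorylation fell from 0.21 to 0.06. The other called lists whose median moved by 1.5 times or more were the tricarboxylic acid cycle (to 0.07), glycolysis (0.09), chaperones (0.10), cholesterol synthesis (0.08), fructose metabolism (0.10), gluconeogenesis (0.05), brush-border peptidases (-0.11), fibroblasts (-0.11), the xenobiotic list (-0.06), the villus tip (-0.02) and crypt base stem cells (-0.35).

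**Figure D2:**
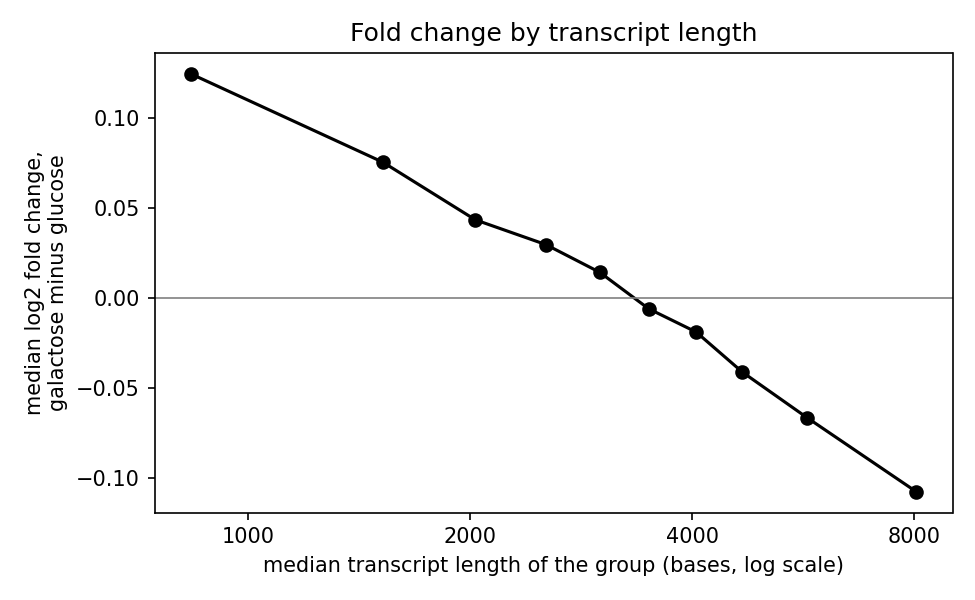
Median log2 difference between the diets in 10 groups of the tested genes by transcript length, against the median length of each group in bases on a log axis. The median went from 0.12 in the shortest group (837 bases) to -0.11 in the longest (8046 bases).

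**Figure D3:**
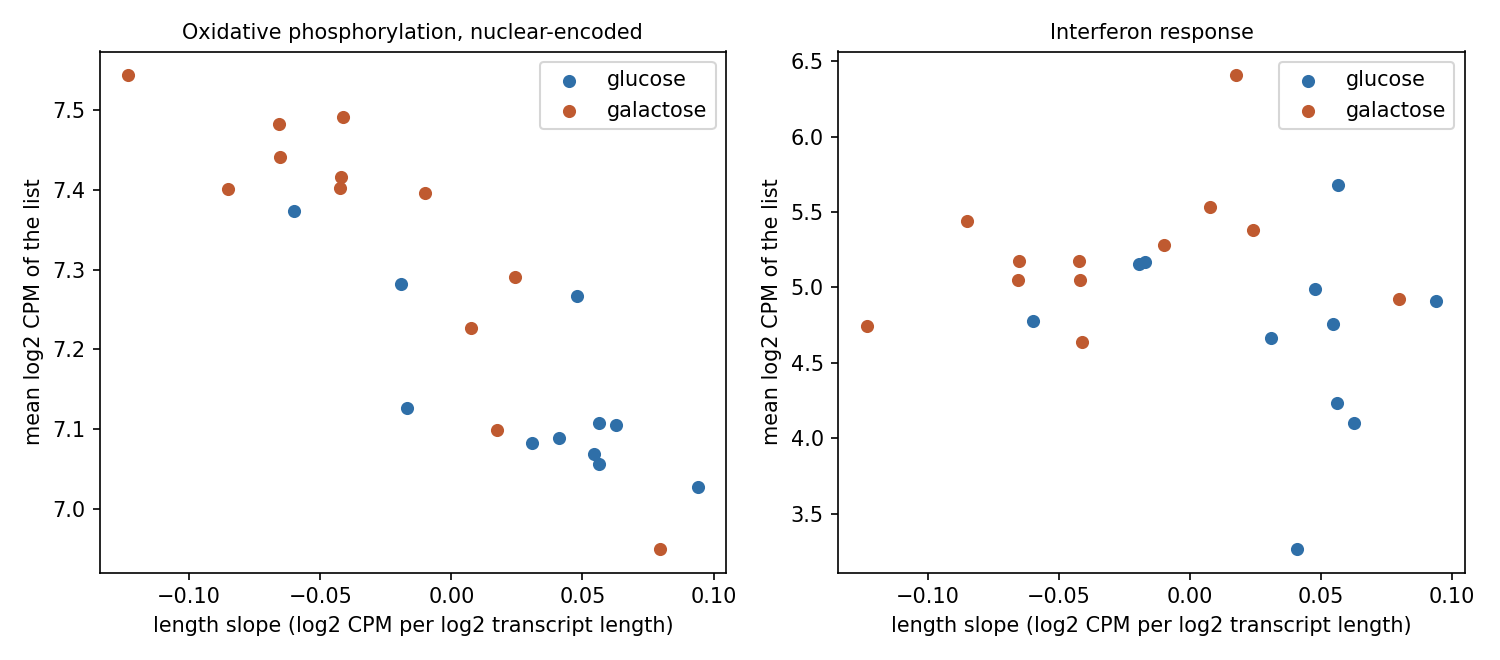
Mean log2 CPM of the oxidative phosphorylation list (left) and of the interferon response list (right) in each library, against the library's length slope in log2 CPM per log2 transcript length, with glucose libraries (n = 11) in blue and galactose libraries (n = 12) in orange. Oxidative phosphorylation scores went down with the slope in both diets, with galactose replicate 7 at the highest slope on galactose, 0.0795, and the interferon scores ran from 3.27 to 6.41.

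Lists of interferon response, antigen presentation and T cell genes were also called higher by camera at its preset correlation, but not with an estimated one. Macrophage and dendritic cell genes (11 of 18 lower, median -0.10) and type 2 immunity genes (7 of 8 lower, median -0.07) were not called. All 31 members of the interferon response list had positive differences (median 0.48), and 9 passed by edgeR when adjusted over the list alone. Over all genes tested 0 passed by edgeR, while Bst2 did by DESeq2 and by edgeR without galactose replicate 7, and Bst2 and Oas1a by limma-voom with quality weights. They included the antiviral genes Bst2 (0.94 ± 0.23), Oas1a (0.73 ± 0.20) and Mx2 (0.77 ± 0.24) and the regulator Irf7 (0.56 ± 0.17). Antigen presentation genes were higher in 19 of 19 members (median 0.22), with H2-D1 (0.38 ± 0.09), Psmb8 (0.32 ± 0.09), Psmb9 (0.40 ± 0.12) and H2-K1 (0.23 ± 0.08) at the smallest p. Markers of T cells and intraepithelial lymphocytes were higher in 22 of 24 members (median 0.39), such as Lck (0.56), Trbc2 (0.60), Cd5 (1.04) and Trac (0.60). With an estimated correlation the adjusted p was 0.439 for the interferon list, 0.387 for antigen presentation and 0.439 for T cells. With surrogate variables as covariates the T cell list turned to a median of -0.10 and antigen presentation to -0.000658, with Psmb9 at -0.0183. Chaperones and folding enzymes of the endoplasmic reticulum (median 0.16, 17 of 20 higher) included Manf (0.34), Pdia6 (0.24), Sdf2l1 (0.25) and Dnajb11 (0.18), at an adjusted p of 0.439 with an estimated correlation. Cholesterol synthesis genes (median 0.16, 20 of 25 higher) included Mvk (0.34), Mvd (0.36), Cyp51 (0.30) and Lss (0.28), at 0.530 for the same adjusted p.

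Lists of peptidases and of peptide transporters were lower on galactose by camera at its preset correlation, while the permutation test of their scores gave an adjusted p of 0.203 and 0.190. In the brush-border peptidase list 11 of 12 members had negative differences (median -0.21, and -0.11 with the length slope as covariate), and 5 passed when adjusted over the list alone. Mep1a had -0.47 ± 0.14, Ace -0.33 ± 0.10, Naaladl1 -0.48 ± 0.17 and Anpep -0.33 ± 0.13. All 14 peptide and amino acid transporters were lower (median -0.15), but 0 passed over the list alone, and 4 had an unadjusted p under 0.05, the peptide transporter Slc15a1 (-0.33), Slc16a10 (-0.22), Slc7a7 (-0.14) and Slc7a15 (-0.21). Both lists had an adjusted p of 0.439 with an estimated correlation. Members of the glutathione and NRF2 list went both ways (15 of 19 lower and 4 higher, of which 6 and 1 passed over the list alone; median -0.16, adjusted p = 0.482 with an estimated correlation). Those of smallest p were Gsta3 (-0.81), Gstm2 (-0.36), Gstm1 (-0.61) and Ces1g (-0.65). The xenobiotic list (median -0.15, adjusted p = 0.601 likewise) held Ces2a (-0.55), Aldh1a1 (-0.49), Cyp3a25 (-0.19) and Tiparp (0.10). Villus-tip genes (median -0.12, adjusted p = 0.540 likewise) included Nt5e (-0.63), Slc28a2 (-0.30), Egfr (-0.20) and Fgf15 (-0.84). With surrogate variables Nt5e turned to 0.0266 and Slc28a2 to 0.00639, and with the length slope Slc28a2 turned to 0.0232.

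Marker lists of crypt base stem cells, fibroblasts and smooth muscle were called lower by camera at its preset correlation, but 0 of their members passed over the list alone, and the permutation test of their scores gave a p of 0.162, 0.207 and 0.293. Crypt base stem cell markers had a median of -0.24, with Axin2 (-0.31), Ascl2 (-0.76), Lgr5 (-0.34) and Slc12a2 (-0.32), and an adjusted p of 0.530 with an estimated correlation. Fibroblast and matrix genes had a median of -0.21, with Fn1 (-0.36), Pdpn (-0.34), Bgn (-0.27) and Postn (-0.47), and smooth muscle genes -0.20, with Cald1 (-0.33), Cnn1 (-0.43), Synpo2 (-0.28) and Myh11 (-0.35). With an estimated correlation the adjusted p was 0.581 for fibroblasts and 0.627 for smooth muscle.

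**Figure D4:**
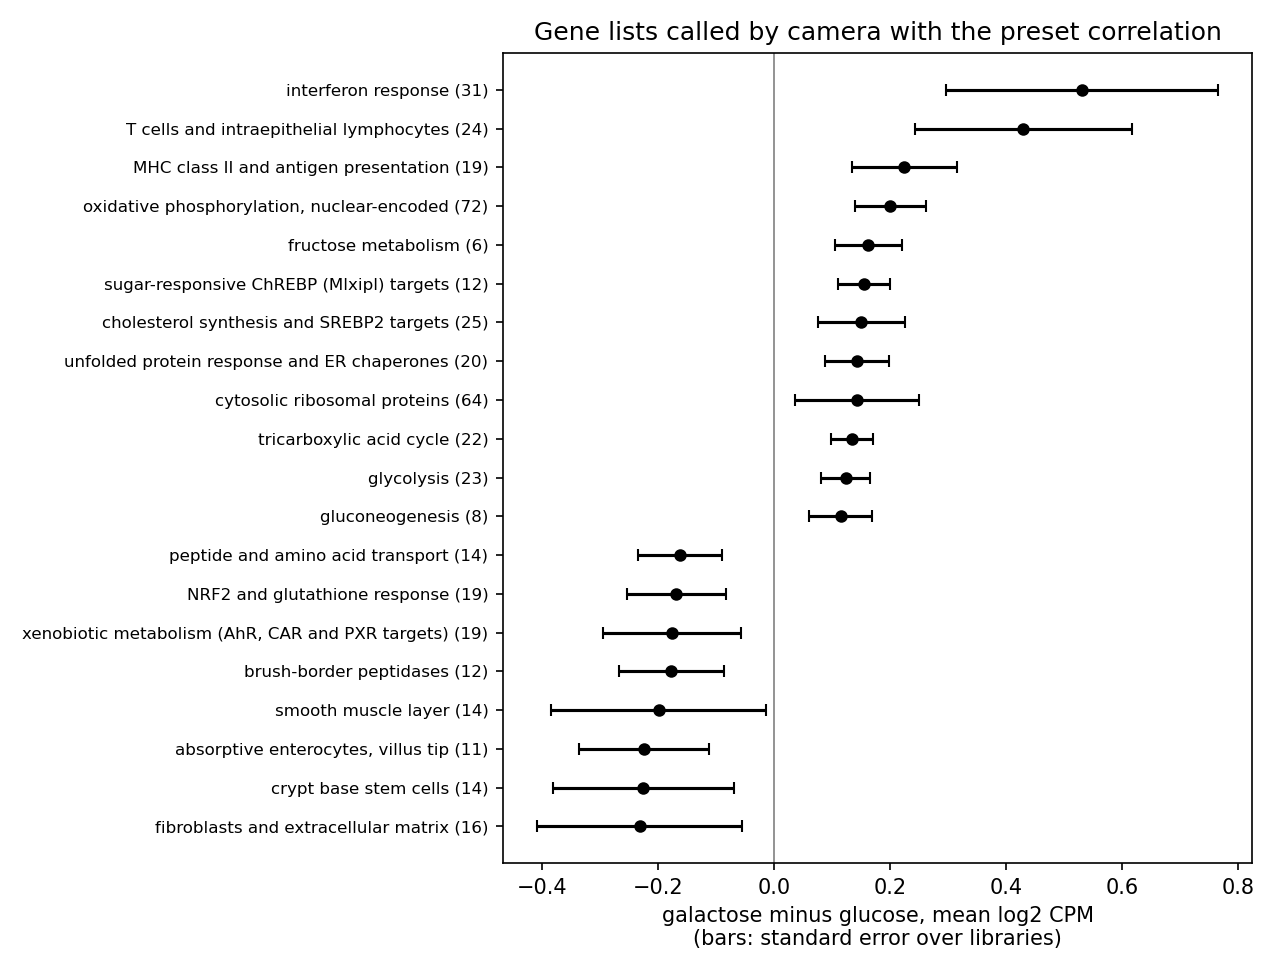
Difference between the diets in the mean log2 CPM of each of the 20 lists called by camera at its preset correlation, with the number of tested members in parentheses and bars of 1 standard error over the 23 libraries. The interferon list had the largest difference, 0.53, and with an estimated correlation 0 of the 20 were called.

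The genes that break down galactose itself showed small differences, and 0 of 8 passed by edgeR. In the Leloir pathway, which turns galactose into glucose phosphate, Galt had 63.7 ± 4.79 CPM on galactose and 57.1 ± 5.37 CPM on glucose (log2 difference 0.16 ± 0.05, unadjusted p = 0.0072, adjusted p = 0.205 by edgeR). Galk2 stood at 0.13 ± 0.05, Galk1 at 0.15 ± 0.09, Pgm1 at 0.09 ± 0.06, Ugp2 at 0.04 ± 0.05, Galm at -0.04 ± 0.05 and Pgm2 at -0.11 ± 0.09. The list had a median of 0.11 and 6 of 8 members higher, at an adjusted p of 0.065 by camera at its preset correlation. Of 10000 random lists matched on length and expression, 92.1% lay below the median of this list. Its score lay above the glucose median in 10 of 12 galactose libraries. The permutation test of its scores gave a p of 0.0244 (adjusted p = 0.162). The interferon, T cell and antigen presentation lists, which camera called, had the same adjusted p of 0.162 by that test. With the length slope as covariate Galk1 stood at -0.0064 and Pgm2 at 0.02.

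Of the sugar transporters 0 of 12 passed, and 8 of 12 were higher. Slc5a1, the sodium-coupled carrier of glucose and galactose, had 4546 ± 780 CPM on galactose and 3825 ± 399 CPM on glucose (0.25 ± 0.09, adjusted p = 0.203 by edgeR). Slc5a4b stood at -0.47 ± 0.17, Slc2a7 at 0.24 ± 0.14, Slc2a2 at 0.14 ± 0.09, Slc5a4a at 0.15 ± 0.14, Slc2a8 at 0.13 ± 0.10 and the fructose carrier Slc2a5 at 0.13 ± 0.12. The remaining Slc2a9, Slc5a9, Slc2a1, Slc5a11 and Slc2a10 lay between -0.01 and 0.04, and each changed sign under some alternative. Slc5a4a and Slc5a4b are close copies, and reads that align to both may be counted for neither. Among the disaccharidases, lactase (Lct) had 4413 ± 757 CPM against 5152 ± 876 CPM (-0.22 ± 0.10, adjusted p = 0.308 by edgeR). Sis stood at 0.16 ± 0.09, Mgam at 0.06 ± 0.12, Mgam2-ps at -0.22 ± 0.12 (0.0393 with the length slope) and Treh at 0.03 ± 0.08 (-0.0310 with surrogate variables). Camera gave that list the lower direction although its median was 0.03 (adjusted p = 0.731).

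Shares of counts from other tissue passed no permutation test between the diets, smooth muscle included, although camera called its list lower at the preset correlation (adjusted p = 0.0298). The share of counts was 0.366 ± 0.0555% on galactose and 0.369 ± 0.0316% on glucose for pancreatic acinar genes, 0.0406 ± 0.00456% and 0.0438 ± 0.00711% for smooth muscle, and 0.0684 ± 0.00438% and 0.0689 ± 0.00439% for adipose tissue. It was 0.000996 ± 0.000274% and 0.00101 ± 0.000379% for blood, 4.95 ± 0.780% and 5.15 ± 0.983% for mitochondrially encoded transcripts, and 0.166 ± 0.0895% and 0.151 ± 0.0565% for B and plasma cells. With the library total and the share of reads without a gene, 0 of 8 measures differed (smallest adjusted p = 0.928, permutation tests). A share follows its most abundant members, and the pancreatic list holds Zg16, which is also on the goblet cell list. Like shares between the diets thus do not exclude other tissue in a scraping. Single libraries stood out by list score, which weighs each member alike. Galactose replicate 2 had 6.58 for pancreatic acinar genes (means 4.59 on galactose and 4.47 on glucose), while the highest share of these genes on galactose was 0.471%. Glucose replicate 1 had 5.99 for adipose genes (means 4.23 and 4.52). In the adipose list 2 of 6 members passed lower on galactose when adjusted over the list alone. Galactose replicate 12, labelled female, held 4 Xist counts against a median of 1518 in the other libraries, and 225 counts of 4 Y-linked genes. Without it edgeR also called 0 genes, and camera 20 lists.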

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

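The tests in this part were chosen after the results had been seen, except the test of 4 X-linked genes on galactose replicate 12 and the count of calls and the search for a swap on galactose replicate 7, which were set before their values were known; the folds of its calls were looked at afterwards.

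Galactose replicate 12 stood out by Y-linked genes that lie outside the tested set and by Xist. It held 225 counts of the Y-linked genes Ddx3y (78), Uty (29), Kdm5d (37) and Eif2s3y (81), where any other library held at most 1. Xist stood at 0.263% of the median of the other libraries. The tables argue against a mixture of male and female RNA, which would keep Xist near its usual level, and they fit a male animal or tube under this label: of Kdm6a, Kdm5c, Eif2s3x and Ddx3x, which are expressed from both X chromosomes, 3 of 4 were at their lowest of the 23 libraries there (mean log2 difference from the median of the others -0.534). Whether the animal's diet label holds is open, and no biological explanation was tested.

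Short transcripts were higher and long ones lower on galactose, which may account for part of the list differences. For glycolysis and the interferon response, member length predicted 0.00503 of a diet difference of 0.124 and 0.00146 of 0.532. After taking it off, 0.119 (95% interval 0.0320 to 0.206) and 0.531 (0.0497 to 1.01) were left. Their median lengths, 2879 and 3325 bases against 3228 for all tested genes, fixed a predicted shift near 0 beforehand. These values thus argue only against a shift by member length as the whole cause. With the length slope held, 0.0872 (-0.0143 to 0.189, which includes 0) was left for glycolysis, with 0 inside in 20 of 23 fits without 1 library. For the interferon response 0.580 (0.000115 to 1.16) was left, with 0 inside in 17 of 23 such fits. Whether these differences go with the slope in another way stays open. The interferon difference itself is weak, as its interval included 0 without any 1 of 4 libraries (galactose replicate 4 and glucose replicates 1, 5 and 11), whether or not the predicted shift was taken off. The ribosomal difference, 0.143 (-0.0795 to 0.365), included 0 before any correction, so the -0.0947 (-0.266 to 0.0767) left with the slope held and the 0.0647 (-0.118 to 0.247) left by prediction leave its cause open. For oxidative phosphorylation the trend cannot be told apart from the diet, because 0.0540 (-0.0305 to 0.139) of 0.201 was left with the slope held but 0.125 (0.0378 to 0.212) by prediction; a lower share of smooth muscle is argued against there, as 0.189 (0.0555 to 0.323) was left with that score held, and an effect of diet on transcripts by length stays open as untested.

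Of 10000 random lists matched on length and expression, 100% lay below the list median for oxidative phosphorylation, glycolysis and the interferon response. For ribosomal genes 98.2% did, so some matched lists reached that median. That comparison treats genes as independent. Oxidative phosphorylation scores followed the length slope within the galactose libraries (r = -0.881, permutation p = 7e-05, adjusted p = 0.0007; rho = -0.797, p = 0.00283, adjusted p = 0.0224) and were -0.759 without the 2 libraries farthest from the median slope. Within the glucose libraries r was -0.771 (permutation p = 0.00719, adjusted p = 0.0180; rho = -0.727, p = 0.0151, adjusted p = 0.0379) but -0.303 without the 2 farthest, so that relation rests on those libraries. Adjustment was over 10 relations.

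Leaving out galactose replicate 7 raised the count of genes called by edgeR from 0 to 219. That library had the highest length slope on galactose, 0.0795, and lay on the glucose side of the contrast fitted without it, at a score of -1.15. Galactose replicate 10 lay on the glucose side of its own contrast too, at -0.114. A swap with a glucose library stays open: 5 glucose libraries lay on the galactose side of theirs, the farthest at 0.92, short of the size of replicate 7. With the length slope as covariate 0 genes were called without replicate 7, the outcome set beforehand for a length trend. Of the 219 genes, 219 kept their direction and a median of 58.5% of their log2 difference (median size 0.29 before and 0.17 after). Their median SE was 0.0694 and 0.0771, and their median unadjusted p by edgeR 0.000324 and 0.0398. These genes were picked by passing in the same libraries, so their folds do not overturn that outcome. The slope also differed between the diets, so lost calls alone do not decide it. Whether the calls rest on the length trend or on the diet stays open. A mouse that responded differently to the diet was not tested.

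The share of reads assigned to more than 1 gene, outside the gene counts, was 1.44 ± 0.0584% on galactose and 1.38 ± 0.0428% on glucose (permutation p = 0.0149, adjusted p = 0.0446 over the 6 added measures).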

How the results depend on the processing

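The length slope, the GC slope and the permutation test of list scores were chosen after seeing the data. Of 17 settings other than leaving out a library, 13 called 0 genes. The others called 87 (64 higher, 23 lower) with DESeq2, 167 (142 and 25) with limma-voom and sample quality weights, 5 (3 and 2) with surrogate variables (Fbp1, Paqr7, Ppm1j, Ces2b and Akr1c14, the last 3 named after their values were seen), and 1, Kctd14, higher with the smooth muscle score as covariate; why they called more was not tested. DESeq2 shared 80 calls with the fit without galactose replicate 7, and quality weights 145. In each of these sets the genes called higher had shorter transcripts by median than those called lower. Leaving out each library in turn gave 0 to 219 genes, 0 to 175 higher and 0 to 44 lower, and only replicate 7 gave any. Camera at its preset correlation called 18 to 26 lists in 11 settings and 19 to 26 with 1 library left out. With an estimated correlation it called 0, on the same counts and design with only the correlation setting changed. For the called lists that correlation was estimated at 0.0745 (gluconeogenesis) to 0.820 (ribosomal genes), against the preset 0.01. It was 0.646 for oxidative phosphorylation and 0.771 for the interferon response. fry called 4 and the permutation test 0. Those tests differ from camera in more than how they treat genes that move together, and why they called fewer was not tested. Of the 8 planned composition measures 0 were called under each alternative.

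Directions turned both for genes near 0 and for others, and the cause was not tested. With quality weights, Slc5a9 stood at -0.000250, Slc2a1 at 0.00856 and Slc5a11 at 0.000748. With surrogate variables, Slc2a10 stood at 0.0943, Treh at -0.0310, Psmb9 at -0.0183, Nt5e at 0.0266, Slc28a2 at 0.00639, the T cell list at -0.0954 and the antigen presentation list at -0.000658. With the smooth muscle score, Slc2a9 stood at -0.0111, Slc5a9 at -0.0102, Slc2a1 at 0.0353, Slc2a10 at 0.000311 and Treh at -0.00277. With gut position, Slc5a11 stood at 0.0208 and Slc2a10 at 0.00209, and with the GC slope, Treh at -0.00512. With the length slope, Galk1 stood at -0.00642, Pgm2 at 0.0174, Mgam2-ps at 0.0393, Rps15 at -0.0468, Rps14 at -0.0470, Rps25 at -0.00222, Slc28a2 at 0.0232 and the ribosomal list at -0.0955. By medians, blood stood at -0.106, mitochondrial transcripts at 0.0115 and B and plasma cells at -0.154 (log2).

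With 1 library left out in turn, 7 named genes crossed 0. Slc2a9 ranged from -0.00125 to 0.0731, Slc5a9 from -0.00894 to 0.0539, Slc2a1 from -0.0434 to 0.0374, Slc5a11 from -0.0281 to 0.0171, Slc2a10 from -0.0830 to 0.0330, Mgam from -0.00643 to 0.106 and Treh from -0.0158 to 0.0583. The log2 difference ranged from -0.0191 to 0.0140 for reads in rows that name no gene, from -0.0818 to 0.120 for blood and from -0.0468 to 0.170 for B and plasma cells.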

Other observations

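Genes of fatty acid synthesis lay lower on galactose, but were not called as a list. The de novo fatty acid synthesis list had a median log2 difference of -0.09 and 11 of 14 members lower on galactose, its mean lay below the glucose median in 11 of 12 galactose libraries, and 2 members passed when adjusted over the list alone. Its member of smallest p, Me1, was called over all genes by DESeq2, limma-voom with quality weights and edgeR without galactose replicate 7. Camera gave the list an adjusted p of 0.1 at the preset correlation. The permutation test of its scores gave a p of 0.0102 (adjusted p = 0.11), so the list passed neither. Glucose replicate 1 had the highest score of this list, 5.25, where the means were 4.66 on glucose and 4.46 on galactose. The same library had the highest adipose score, 5.99. The permutation test was not repeated without that library. Genes of the suckling intestine (median 0.08, adjusted p = 0.413) and of the mature intestine after weaning (median 0.03, adjusted p = 0.960) were not called. Nor were goblet cell genes (median -0.08, 10 of 13 lower, adjusted p = 0.0621), Paneth cell genes (median -0.24, 15 of 15 lower, adjusted p = 0.1) or B and plasma cell genes (median 0.28, 13 of 13 higher, adjusted p = 0.0502).

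The interferon scores varied widely within each diet, 5.23 ± 0.457 on galactose and 4.70 ± 0.643 on glucose (mean log2 CPM, SD). Glucose replicate 11 had the lowest score, 3.27, and galactose replicate 4 the highest, 6.41. Holding the length slope, the diet difference was 0.40 (95% interval -0.141 to 0.951) without galactose replicate 4 and 0.45 (-0.0338 to 0.938) without glucose replicate 11. The interval included 0 in 17 of the 23 such fits, all but those without galactose replicates 7 and 10 and glucose replicates 3, 6, 7 and 8.

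Splits of the libraries into groups of 12 and 11 were compared with the real one, all after the counts were known. For the 0 genes called by edgeR, 100 of 100 splits gave as many, as any count does against 0, so this comparison tests nothing. The highest other split gave 125, and its groups differed in the length slope by 0.0753. Another split whose groups differed in it by 0.0650 gave 0. Over the splits, the size of the slope difference went with the number of genes at an unadjusted p under 0.05 (Spearman 0.477). Why 1 split gave 125 was not tested. For the 1924 genes at an unadjusted p under 0.05, 3 of 100 splits gave as many. The highest other gave 2727, so a random split can exceed the real count. For the 20 lists of camera, 28 of 100 splits gave as many, the highest other 29, so chance is not excluded, and the other splits called a median of 15. For the 4 lists of fry, 2 of 100 gave as many, and the highest other, at 6, likewise exceeded the real count. For the 87 genes of DESeq2 it was 1 of 30, the smallest share that 30 splits can give, and the highest other was 25. These shares were not adjusted over the 5 counts, so the small ones make chance less likely but do not exclude it. These counts set the real groups against random ones and do not separate the diet from the length slope, in which the diets also differed (adjusted p = 0.0446).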
